A study of Mus musculus with 20 samples.

How the data were processed

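RNA was measured in LT-HSCs sorted from lineage-depleted bone marrow as Lin-, Sca-1+, CD117+, CD135-, CD150+ and CD48- cells, with a SMART-Seq v4 low-input library kit per the labels. The deposited tables hold raw read counts per Ensembl gene; per the labels, the authors used bcl2fastq, STAR, featureCounts and DESeq2 1.20 with build GRCm38, and no normalization was applied to the counts. The roles and parameters of these tools, the annotation release and the strand setting are not stated in the labels. There were 2 count tables, 1 for each age, with 53379 genes each. Of these, 53274 (99.8%) matched the gene models used here for positions, exon lengths and overlaps, which need not be the release the authors used. Every count column matched a library and was a whole number.

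Libraries were grouped by age and genotype from the labels: 6 per genotype at 24 months and 4 per genotype at 16 weeks. The comparisons were aged KO with aged WT, young KO with young WT, the difference between these effects, aged with young WT and aged with young KO. Genes were filtered with filterByExpr, scaled by TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The KO comparisons were fitted within an age and the others over all 4 groups. Levels are TMM-scaled CPM, except values of single libraries and their means for Phf6, S100a8 and Igkc, which are counts over the library total alone. Log2 values for lists used a prior count of 2.

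For 34 gene lists from prior knowledge, camera of limma 3.58.1 was run with a preset correlation of 0.01 where at least 5 members were tested, beside camera with an estimated correlation and fry. List scores are the mean centred log2 CPM per library, compared by exact two-sided permutation tests over all splits of the libraries. The comparisons, lists, gene and list tests and naming rule were fixed before the data were examined. So were the scores, within each age, of the lists of genes known to rise or fall with age in stem cells. Scores of the other lists, differences of scores between ages and permutation tests of principal components were not in that plan. The rule names Phf6 and, per comparison, up to 10 genes per direction (5 for the difference between ages) with an adjusted p under 0.05, a mean of at least 5 CPM, every library on one side of the other group's mean (dropped for the difference between ages) and a symbol that is not a predicted gene, clone, pseudogene or ribosomal protein gene. It adds up to 4 members per list by p and, in the KO comparisons, Selp, Vwf, Slamf1, Aldh1a1, Nupr1, Clu, Procr, Cdkn1c, Mki67, Fos, Nfkbia and Flt3. Some genes the rule chose are not reported here.

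Alternatives were other scalings and filters, DESeq2 1.42.0, limma voom with and without quality weights, a 2-fold minimum, a replicate block, other fits of the groups, leaving out mitochondrially encoded and haemoglobin genes, and leaving out each library. An offset for gene length and GC content and leaving out aged KO replicates 5 and 6 together were added after the data were seen. A sex covariate was not run, since every library had Y-linked and almost no Xist counts. Simulated data held genes changed 1.5-, 2- or 4-fold. Of the 2-fold changes the test called 83.6% in aged mice, 83.6% in young mice and 46.3% for the difference between ages. Of the 1.5-fold changes it called 52.2%, 32.8% and 22.4% in the same order, so smaller changes were found less often in young mice. Of all calls, 3.75%, 4.64% and 4.04% were false. Library totals limit the precision of low counts, and PCR copies without molecular identifiers are not independent molecules.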

Results

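RNA was sequenced from long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that sustain blood formation over a lifetime, of C57BL/6 mice. The mice were wild type (WT) or knockout (KO) for Phf6, an X-linked gene whose product is a chromatin-associated protein with PHD-like zinc fingers. Young mice were 16 weeks old and aged mice 24 months old. There were 6 aged WT, 6 aged KO, 4 young WT and 4 young KO libraries. Total counts ran from 10869693 to 18665344 per aged library and from 6293783 to 19297867 per young library. Between 20835 and 22172 genes had counts in the aged libraries and between 18499 and 19743 in the young ones. In all 20 libraries Xist was at or below 0.644 CPM (counts scaled to the library total), and the summed Y-linked genes were at 162 CPM or more. The series title and design ask how loss of Phf6 bears on the changes of expression that come with age in these cells.

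Phf6 (ENSMUSG00000025626.16) lies on the plus strand of chromosome X, from 52912266 to 52956943 in GRCm38, with 6946 bases of annotated exon. In the aged WT libraries it stood at 119, 135, 117, 118, 118 and 127 CPM (mean 122 ± 7.28, SD, n = 6). In the aged KO libraries it stood at 16.0, 20.4, 16.1, 24.7, 54.3 and 53.1 CPM for replicates 1 to 6, which averaged 25.1% of the aged WT mean. In the young WT libraries it was 90.6, 103, 103 and 127 CPM (mean 106 ± 15.4, SD, n = 4). The young KO libraries held 20.7, 15.3, 19 and 18.2 CPM, 17.3% of the young WT mean. The log2 fold change of Phf6 was -2.00 ± 0.32 (SE) in aged mice (adjusted p = 0.00237) and -2.53 ± 0.13 in young mice (adjusted p = 7.73e-07). All 10 KO libraries lay below all WT libraries of their age. Aged KO replicates 5 and 6 kept more Phf6 counts than the rest, and without both of them the aged log2 fold change was -2.64. The labels do not say which part of the gene was removed, so counts over the whole gene can include reads from exons outside that part.

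**Figure D1:**
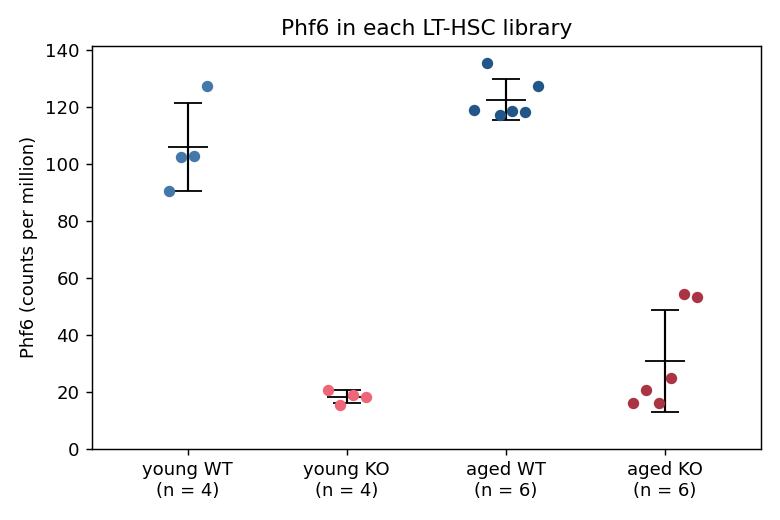
Phf6 in CPM (y axis) for each library, by age and genotype (x axis). Each point is 1 library and the black bar and whiskers are the mean ± SD. The KO libraries lie between 15.3 and 54.3 CPM and the WT libraries between 90.6 and 135 CPM.

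The comparison of aged KO with aged WT asks what loss of Phf6 changes in old stem cells. Aged KO cells had 16.7-fold more Ccn1, a secreted matricellular protein (20.7 ± 12.7 against 1.26 ± 1.03 CPM, SD, n = 6 each). Ndnf, a secreted neurotrophic factor, was 16.3-fold higher, and Ptprb, a receptor phosphatase best known from endothelium, was 10.9-fold higher. Aged KO cells had 11-fold less Spint1, an inhibitor of serine proteases (2.01 ± 2.09 against 21.8 ± 2.97 CPM), and 7.75-fold less Gpr183, an oxysterol receptor (12.4 ± 8.52 against 95.5 ± 17.2 CPM). Of 58 genes known to rise with age in stem cells 25 fell, among them Selp, Slamf1, Clu and Nupr1, while 27 of 53 interferon response, 12 of 28 cholesterol synthesis and 11 of 40 ribosome biogenesis genes rose. As lists these 4 passed camera with a preset correlation but not with an estimated one (adjusted p = 0.461 each).

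Of 14973 genes tested, 1758 differed at an adjusted p under 0.05, 748 higher and 1010 lower in aged KO, and 395 of them by at least 2-fold. With upper quartile scaling the split was 572 higher and 1209 lower. The first principal component of the 12 aged libraries separated the genotypes (exact permutation p = 0.00216, two-sided, the smallest that 924 splits allow).

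Among the genes that met the naming rule, which asks for a mean of at least 5 CPM, Ccn1 (log2 fold change 4.06 ± 0.69, SE, adjusted p = 0.00331; chromosome 3, 145646976 to 145649981) had the largest rise. Ndnf followed at 4.03 ± 0.60 (adjusted p = 0.00144; chromosome 6, 65671590 to 65712326) and Ptprb at 3.45 ± 0.25 (adjusted p = 6.45e-07; chromosome 10, 116275523 to 116389535). Nrk, a kinase gene, rose from 5.70 ± 2.24 to 39.5 ± 12.9 CPM, and the adaptor gene She from 1.75 ± 0.58 to 10 ± 3.66 CPM. Stxbp6 (1.96), the mitochondrial subunit gene Cox4i2 (1.90), the death receptor gene Tnfrsf25 (1.83), the adhesion receptor gene Adgre4 (1.75) and Cd248 (1.71), the endosialin gene, completed the 10 largest rises under that rule. Their adjusted p values lay between 6.45e-07 and 0.0101.

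Spint1 (log2 fold change -3.46 ± 0.47, adjusted p = 0.000557; chromosome 2, 119237362 to 119249527) had the largest drop under the same rule. The lectin gene Zg16 fell from 38 ± 9.77 to 3.65 ± 4.15 CPM and the keratin gene Krt80 from 9.85 ± 5.35 to 0.958 ± 0.694 CPM. Reads of Krt80 could not be told from those of the antisense gene Gm35853, because the library kit does not mark strand. Gpr183 (-2.95 ± 0.39, adjusted p = 0.000696; chromosome 14, 121952551 to 121965195), Rcvrn (-2.73), the epithelial adhesion gene Epcam (-2.44), the short-chain fatty acid receptor gene Ffar2 (-2.43) and the imprinted gene Dlk1 (-2.40) followed. The mucin gene Muc1 (-2.38) and the desmosomal gene Dsc2 (-2.38) closed the group. The naming rule itself requires all 6 aged KO libraries on the same side of the aged WT mean for each of these 20 genes.

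**Figure D2:**
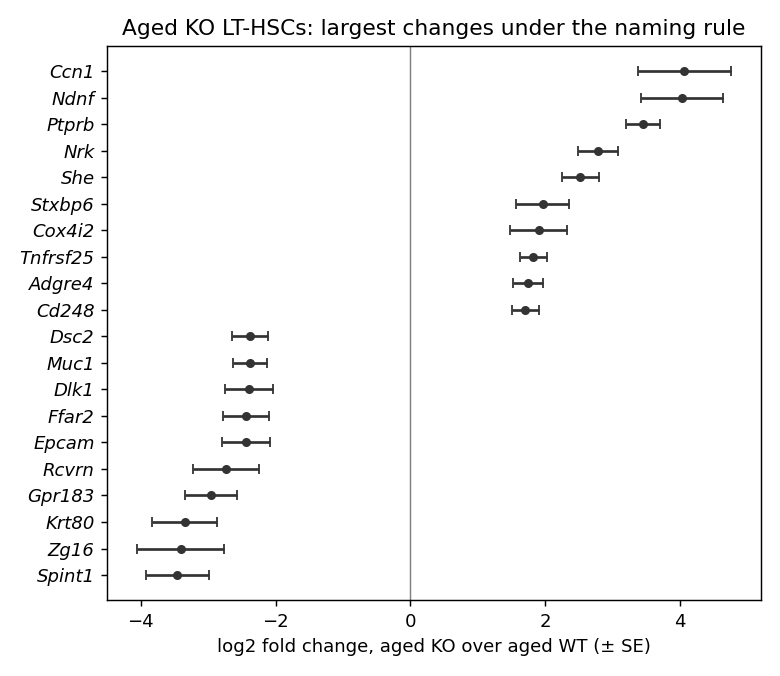
Log2 fold change of aged KO over aged WT (x axis) with its standard error for the 10 genes that rose most and the 10 that fell most among those that met the naming rule, with a mean of at least 5 CPM (y axis), n = 6 libraries per genotype. Values run from -3.46 for Spint1 to 4.06 for Ccn1.

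Of the 58 genes in the list known to rise with age in stem cells (HSC ageing up), 25 fell and 1 rose in aged KO, and 32 did not pass the test. The counts adjusted over the list alone were 28 lower and 1 higher. Their median log2 fold change was -0.41 (camera adjusted p = 1.51e-11, but adjusted p = 0.461 with an estimated correlation). Selp, which encodes P-selectin, fell from 436 ± 42.3 to 215 ± 33.7 CPM (log2 fold change -1.02 ± 0.10, adjusted p = 1.83e-05), and it overlaps antisense genes. Osmr, the oncostatin M receptor gene, fell from 24.5 ± 2.86 to 5.60 ± 1.91 CPM, and the desmoglein gene Dsg2 from 43.9 ± 3.87 to 15.1 ± 3.63 CPM. Slamf1 (-0.78 ± 0.09), which encodes the sorting marker CD150, Clu (-0.96 ± 0.12), Nupr1 (-1.15 ± 0.11) and Enpp5 (-0.72 ± 0.07) fell too. Vwf (0.13, adjusted p = 0.499), Aldh1a1 (-0.09, adjusted p = 0.442) and Fos (1.36 ± 1.14, adjusted p = 0.52) of the same list did not pass. As a score, the mean centred log2 CPM of the list was 0.47 lower in aged KO, with 6 of 6 KO libraries below every WT library (exact permutation p = 0.00216, two-sided, the smallest possible; adjusted p = 0.0294 over 34 lists).

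In the list of genes known to fall with age (HSC ageing down), 3 of 28 fell and 1 rose (adjusted over the list alone, 4 and 1), and the score differed by -0.11 (exact permutation p = 0.526, camera adjusted p = 0.429). Flt3, the gene of the CD135 protein that the sort excluded, fell from 17.7 ± 3.90 to 7.27 ± 2.19 CPM. Kit fell from 1866 ± 195 to 1360.3 ± 160.4 CPM and lost its call when all 4 groups were fitted together. In the LT-HSC identity list 9 of 30 genes fell and 1 rose (adjusted over the list alone, 11 and 4), among them Lmo2 (-0.35) and Mllt3 (-0.41), with camera adjusted p = 0.058. Procr (-0.32, adjusted p = 0.0825) and Cdkn1c (0.17, adjusted p = 0.42) did not pass. In the list of cytokine receptors and JAK-STAT genes 8 of 31 fell and 1 rose (adjusted over the list alone, 8 and 2; camera adjusted p = 0.253), including Il1r1 (-1.30 ± 0.13) and Csf3r (-0.52 ± 0.09).

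Interferon response genes rose as a group, with 27 of 53 higher and 1 lower, or 35 higher and 1 lower adjusted over the list alone (median log2 fold change 0.38, camera adjusted p = 7.07e-13, adjusted p = 0.461 with an estimated correlation). Mx1, an antiviral GTPase gene, rose from 1.86 ± 0.79 to 6.39 ± 1.45 CPM, Rsad2 from 34.7 ± 4.99 to 57.3 ± 11.3 CPM and Gbp7 from 182 ± 24.5 to 259 ± 28.3 CPM. Ly6e was the member that fell (-0.41 ± 0.06). The interferon score was 0.47 higher in aged KO, with 5 of 6 KO libraries above every WT library (exact permutation p = 0.00433, two-sided; adjusted p = 0.0294).

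In the cholesterol and fatty acid synthesis list 12 of 28 genes rose and 0 fell in the edgeR test (19 higher and 1 lower adjusted over the list alone; median 0.54, camera adjusted p = 5.56e-09, adjusted p = 0.461 with an estimated correlation). Hmgcs1 rose from 39.9 ± 8.77 to 67.0 ± 9.64 CPM and Sqle from 98.2 ± 22.2 to 165 ± 36.1 CPM. Ribosome biogenesis genes were higher in 11 of 40 (18 adjusted over the list alone), with Utp15 at 0.24 and Nolc1 at 0.26 (camera adjusted p = 1.12e-07, adjusted p = 0.461 with an estimated correlation). MYC targets were higher in 11 of 30 (13 adjusted over the list alone), with Srm at 0.45 and Mybbp1a at 0.27 (camera adjusted p = 2.94e-07, adjusted p = 0.461 with an estimated correlation). The ribosome biogenesis and MYC lists share members, among them Ncl and Nolc1. Utp15 and Mybbp1a lost their calls with all 4 groups in the fit, and Nolc1 there and without aged KO replicates 5 and 6. Scores of these 3 lists differed by 0.44, 0.17 and 0.19 (exact permutation p = 0.00433 each; adjusted p = 0.0294). The score of TGF-beta and BMP genes differed by 0.17 as well (exact permutation p = 0.00649, adjusted p = 0.0368), although that list did not pass camera.

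The smaller list calls were less firm. Lysosome and autophagy genes were lower in 4 of 32 (5 adjusted over the list alone), such as Hexa (-0.25) and Lamp2 (-0.26; camera adjusted p = 0.00484, adjusted p = 0.708 with an estimated correlation). HOX and cofactor genes were lower in 3 of 17, also when adjusted over the list alone, with Meis1 at -0.21 (camera adjusted p = 0.0353, adjusted p = 0.461 with an estimated correlation). That call was lost, at adjusted p up to 0.0803, without aged KO replicate 1, 5 or 6 or aged WT replicate 4. Heat shock and unfolded protein response genes were higher in 3 of 33, also when adjusted over the list alone, among them Hspe1, Hspd1 and Hspb1 (camera adjusted p = 0.0201, adjusted p = 0.75 with an estimated correlation). Hspe1 and Hspd1 share a locus in antisense orientation, and the list call was lost, at adjusted p up to 0.083, without aged KO replicate 6 or aged WT replicate 6. Mitochondrially encoded genes were 0.418% ± 0.0589 of counts in aged KO and 0.504% ± 0.0439 in aged WT. The list was lower as a group (median -0.20, camera adjusted p = 0.038, adjusted p = 0.75 with an estimated correlation) with 0 of 12 genes called by edgeR and 0 adjusted over the list alone. It was no longer called, at adjusted p up to 0.181, without aged KO replicate 1, 2, 4 or 6 or aged WT replicate 1 or 6.

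The 25 other lists did not pass camera in aged mice. Among markers of other cells, megakaryocyte and platelet genes had 4 of 29 higher, such as Thbs1 (1.52), and 6 lower, such as Itgb3 (-0.76; adjusted p = 0.308). The lymphoid priming list had 3 of 18 lower, including Lsp1 at -1.19 (adjusted p = 0.436). The erythroid list had 1 of 23 lower, Car2 at -0.73 (adjusted p = 0.854), and granulocyte and monocyte markers 2 of 28 lower, with Prtn3 at -0.99 (adjusted p = 0.24). T and NK cell markers had 1 of 6 lower, Gata3 at -0.30 (adjusted p = 0.108), and endothelial and stromal markers 1 of 8 lower, Pecam1 at -0.31 (adjusted p = 0.59). Mast cell, basophil and eosinophil markers had 1 of 13 higher, Il4 at 0.97, and 1 lower (adjusted p = 0.926). B cell and plasma cell markers had 1 of 12 higher, H2-Ab1 at 0.66 (adjusted p = 0.145). Igkc, an immunoglobulin gene of that list, ranged from 67.0 to 752 CPM in the aged KO libraries and from 78.9 to 233 CPM in the aged WT ones (adjusted p = 0.195).

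Cell cycle lists held no called gene in the edgeR test, which gave 3794 genes at an unadjusted p under 0.05 in all, where DESeq2 called 2245 genes and limma voom 1788: 0 of 34 for DNA replication (adjusted p = 0.429) and 0 of 32 for mitosis (adjusted p = 0.577), with Mki67 at -0.14. Quiescence genes had 4 of 19 lower, such as Txnip at -0.73 (adjusted p = 0.308). Immediate early genes had 3 of 25 higher, including Ccn1 and Klf4 (1.12; adjusted p = 0.108). TNF and NF-kappaB genes had 5 of 30 lower, among them Bcl3 (-0.68) and Nfkbia (-0.29), and 2 higher, Cxcl10 (2.26) and Rel (0.62; adjusted p = 0.341). TGF-beta and BMP genes had 3 of 24 higher and 3 lower, including Tgfbi at -1.49 (adjusted p = 0.375). The p53 list had 4 of 30 lower, with Perp at -1.82 (adjusted p = 0.602), and the DNA damage repair list 2 of 32 higher, with Atm at 0.62 (adjusted p = 0.0584). The apoptosis list had 1 of 23 higher, Bcl2l1 at 0.41, and 2 lower, such as Casp6 at -0.41 (adjusted p = 0.614). DNA methylation and polycomb genes had 3 of 27 higher, such as Jarid2 at 0.26 (adjusted p = 0.191), and the NuRD complex 0 of 14 (adjusted p = 0.429). Glycolysis genes had 1 of 20 lower, Slc2a3 at -0.40 (adjusted p = 0.3), nuclear oxidative phosphorylation genes 1 of 50 higher (adjusted p = 0.253), and cytosolic ribosomal protein genes 0 of 77 (adjusted p = 0.794).

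Adjusted over the list alone, the counts differed for megakaryocyte (4 higher, 7 lower), T and NK cell (2 lower), endothelial (2 and 2), quiescence (2 and 6), TNF (2 and 6), TGF-beta (5 and 4), DNA damage (1 higher) and oxidative phosphorylation genes (0). For 7 of these 25 lists the median, the mean and the direction of the test differed in sign: the lymphoid, erythroid, granulocyte, mast cell, p53, apoptosis and cytokine receptor lists. Of the 97 genes called among those chosen by the naming rule, 86 kept their call when each aged library was left out in turn. The 11 others, among them Bcl2l11, Cdkn1a, Gadd45a, Gata2, Heatr1, Hoxa9, Klf6, Ncl, Parp1 and Pdk4, each lost it without 2 to 9 of the 12 libraries, at adjusted p up to 0.116.

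**Figure D3:**
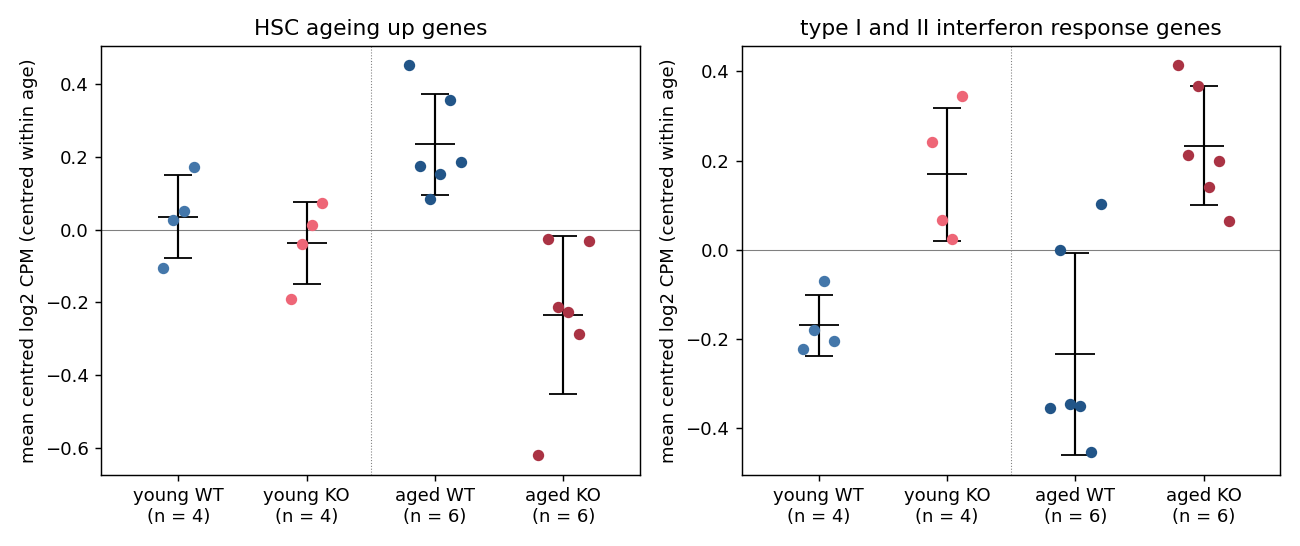
Mean log2 CPM of the genes of 2 lists in each library, centred on 0 within each age (y axis), by age and genotype (x axis). Points are libraries and bars are mean ± SD. The ageing list differed by -0.47 between aged genotypes and by -0.07 between young ones, and the interferon list by 0.47 and 0.34.

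In young mice, 26 genes were called. Young KO cells had 3.78-fold less Bcam, a laminin receptor gene (6.18 ± 1.08 against 23.0 ± 2.53 CPM, SD, n = 4 each). The detoxification genes Gstm2 and Sult1a1 and the haem oxygenase gene Hmox1 fell by 1.44, 1.37 and 1.21 on the log2 scale. Ifit3, an interferon-induced antiviral gene, was 3.35-fold higher (19.7 ± 7.52 against 5.81 ± 0.86 CPM), and Ifi44, another interferon-induced gene, rose from 70.2 ± 7.87 to 121 ± 15.4 CPM.

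Of 13174 genes tested, 26 differed at an adjusted p under 0.05, 11 higher and 15 lower, against 732 at an unadjusted p under 0.05. Bcam (-1.92 ± 0.18, SE, adjusted p = 0.000364; chromosome 7, 19756131 to 19771016) overlaps the antisense gene Gm26600. Ifit3 (1.74 ± 0.27, adjusted p = 0.0263; chromosome 19, 34583531 to 34588731) had the largest rise among the genes that met the naming rule, with a mean of at least 5 CPM. The others under that rule were Mum1l1 (1.36), Fndc4 (1.07), Phf11d (0.99), the protease gene Ctsw (0.99), Ccdc60 (0.97), Ifi44 (0.78) and the MHC class II gene H2-Ab1 (0.60). Lower were also Tnip3 (-1.0), Gimap3 (-0.96), Mpzl1 (-0.76), Dok2 (-0.74), Sdsl (-0.69) and Serpinf1 (-0.53). Ctsw and Sult1a1 overlap antisense genes. Selp (-0.97 ± 0.33, adjusted p = 0.579), Slamf1 (-0.38, adjusted p = 0.454), Aldh1a1 (0.41, adjusted p = 0.161) and Procr (-0.30, adjusted p = 0.796) did not pass. Vwf (0.07), Nupr1 (-0.39), Clu (-0.49), Cdkn1c (-0.14), Mki67 (-0.06), Fos (0.80), Nfkbia (-0.06) and Flt3 (-0.15) had adjusted p values of 0.975 or more.

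The count rested on the method and on single libraries. It was 97 with no filter, 105 with DESeq2, 109 with voom quality weights, 55 with all 4 groups in the fit, 15 with a 2-fold minimum and 9 with the replicate block. It was 5, 13, 17 and 2 without young KO replicates 1, 2, 3 and 4, and 4 and 5 without young WT replicates 2 and 3. Of 21 called genes under the naming rule, Phf6 and Bcam kept their call in every such fit, and each of the 19 others lost it in 2 to 8 of the 8 fits. On the first and second principal components of the 8 young libraries the genotypes overlapped (exact permutation p = 0.657 and 0.257).

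Interferon response genes were higher as a group in young KO too, with 2 of 53 called and 8 adjusted over the list alone (median log2 fold change 0.27, camera adjusted p = 8.95e-18, adjusted p = 0.328 with an estimated correlation). Ifit3 and Ifi44 passed, while Irf7 (0.78, adjusted p = 0.0819) and Cxcl10 (1.68, adjusted p = 0.0609) did not. All 4 young KO libraries had an interferon score above every young WT library (difference 0.34, exact permutation p = 0.0286, two-sided, the smallest that 70 splits allow). It did not hold after adjustment over 34 lists (adjusted p = 0.938). A list that alone has that smallest p cannot pass this adjustment, so the adjusted value decides nothing here. Cholesterol synthesis genes were higher with 0 of 28 called and 3 adjusted over the list alone, Msmo1 at 0.51 and Hmgcs1 at 0.47 (camera adjusted p = 7.92e-05, adjusted p = 0.472 with an estimated correlation).

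Genes known to fall with age were lower as a list, with 0 of 28 called and 1 adjusted over the list alone (camera adjusted p = 0.00507, adjusted p = 0.328 with an estimated correlation, adjusted p = 0.0603 without young WT replicate 1). Their score differed by -0.16 (exact permutation p = 0.0571), and by -0.18 without young WT replicate 3 (exact permutation p = 0.0286). DNA replication genes were lower with 0 of 34 called, also when adjusted over the list alone, and Pola1 at -0.40 (camera adjusted p = 0.000437, adjusted p = 0.945 with an estimated correlation). Adjusted p for that list rose to at most 0.367 without young KO replicate 1 or young WT replicate 1, where its call was lost. Of the DNA replication genes, 10 are also in the list of genes known to fall with age.

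Of the marker lists higher in young KO, megakaryocyte and platelet genes had 1 of 29 called, Tubb1 at 1.30, and 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0337, adjusted p = 0.945 with an estimated correlation). That call was lost, at adjusted p up to 0.367, without young KO replicate 1, 2 or 4 or young WT replicate 1. Granulocyte and monocyte genes had 1 of 28 called, Cd14 at 1.56, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0272, adjusted p = 0.945 with an estimated correlation). It was lost, at adjusted p up to 0.528, without young KO replicate 4 or young WT replicate 1 or 3. S100a8 was at 1287 ± 312 CPM in young KO and 1013 ± 329 CPM in young WT. The HSC ageing up list did not pass in young mice (1 of 52 lower, Sult1a1, and 6 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.328), and its score differed by -0.07 (exact permutation p = 0.429). Of the 28 lists that did not pass, 4 had a median, mean and test that differed in sign.

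Whether loss of Phf6 acts differently in aged and young cells was tested as the difference between the effects of the KO at the 2 ages. The RNA-binding protein gene Igf2bp2 (chromosome 16, 22059009 to 22163299) was 31.6 ± 3.26 CPM in aged KO, 13.5 ± 1.63 in aged WT, 15.1 ± 1.73 in young KO and 14.4 ± 1.54 in young WT. The peptidase gene Ggt5 (chromosome 10, 75589340 to 75617200) was 5.90 ± 0.64, 16.1 ± 2.07, 19.5 ± 3.63 and 22.2 ± 1.03 CPM in the same order. The prostaglandin D synthase gene Hpgds was 6.29 ± 1.88 CPM in aged KO and 22.2 ± 7.33 in aged WT, against 5.58 ± 0.52 and 6.59 ± 0.77 in the young genotypes. Of the 58 genes known to rise with age, 2 had a more negative KO effect in aged than in young cells, and the list passed camera with a preset correlation but not with an estimated one (adjusted p = 0.474).

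Of 15869 genes tested, 48 differed, 10 with a more positive and 38 with a more negative KO effect in aged mice. As 8 of 100 splits of the genotype labels gave as many genes, chance is not excluded for that count. Such splits also shuffle the KO effect within each age, so they do not test the difference alone. It was 139 with DESeq2, 100 with voom quality weights, and 30 each with a 2-fold minimum and with the replicate block. Among genes with a mean of at least 5 CPM that met the naming rule, the largest positive differences in log2 fold change were in Gimap3 (2.01 ± 0.41, SE, adjusted p = 0.0345), Adgre4 (1.72 ± 0.36), Neto2 (1.2 ± 0.26), Igf2bp2 (1.16 ± 0.17, adjusted p = 0.00234) and the neurofilament gene Nefh (1.09 ± 0.18). The largest negative ones were in the peptidase gene Dpp4 (-1.76 ± 0.35), Smagp (-1.75 ± 0.31), Pcp4l1 (-1.63 ± 0.27), Hpgds (-1.58 ± 0.33) and Ggt5 (-1.25 ± 0.18, adjusted p = 0.00234). Of 15 called genes under the naming rule, 5 kept their call without each of the 20 libraries in turn, and 10 lost it in 1 to 16 of these fits, at adjusted p up to 0.137. Those 10 were Adgre4, Aldh1a1, Dpp4, Enpp5, Flt3, Gimap3, Hpgds, Neto2, Pcp4l1 and Prtn3. The count of genes was 121 without aged KO replicates 5 and 6, and 74 without aged KO replicate 6. It was 22 and 20 without aged KO replicates 3 and 4, and 30, 22, 27 and 28 without aged WT replicates 1, 3, 4 and 5. Without young KO replicates 1, 2 and 4 it was 24, 16 and 21, and without young WT replicates 1 and 2 it was 12 and 24.

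In the HSC ageing up list, 2 of 58 genes differed, Enpp5 (-0.70 ± 0.13) and Aldh1a1 (-0.51 ± 0.11), and 16 were lower and 2 higher adjusted over the list alone (median -0.39, camera adjusted p = 4.74e-08, adjusted p = 0.474 with an estimated correlation). Aldh1a1 did not pass within either age, and its value in young KO was a rise. Both Enpp5 and Aldh1a1 lost the call for the difference in some fits that left out a single library. The score difference was -0.47 in aged and -0.08 in young mice on the joint scale. The difference between them, -0.39, had an exact permutation p of 0.0401 (two-sided, 64680 arrangements of the genotype labels within ages). It did not hold after adjustment over the 5 scores tested this way (adjusted p = 0.201). Shuffling labels at both ages assumes no KO effect at either age, so p values obtained this way do not test equality of the effects alone. The interferon score differed by 0.13 between the ages (exact permutation p = 0.588), and the ageing down score by 0.03 (exact permutation p = 0.835). Ribosome biogenesis (median 0.22, adjusted p = 4.78e-07), MYC target (0.21, adjusted p = 5.07e-06), cholesterol (0.28, adjusted p = 0.000152) and DNA replication lists (0.21, adjusted p = 0.00195) had a more positive KO effect in aged mice, with 0 genes called by edgeR in each, of 1263 at an unadjusted p under 0.05 in all. These 4 lists had adjusted p = 0.811 with an estimated correlation. The ribosome biogenesis and cholesterol score differences were 0.22 and 0.28, with exact permutation p of 0.124 and 0.191.

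Heat shock (median 0.19, adjusted p = 0.004), DNA damage repair (0.13, adjusted p = 0.0106), immediate early (0.34, adjusted p = 0.012) and interferon lists (0.10, adjusted p = 0.0286) were likewise more positive, with adjusted p = 0.811 with an estimated correlation for each. The lysosome (-0.15, adjusted p = 0.000266), granulocyte (-0.42, adjusted p = 0.0286) and HOX lists (-0.17, adjusted p = 0.0286) were more negative, and their adjusted p was 0.757, 0.811 and 0.757 with an estimated correlation. Several of these calls rested on single libraries among the 20. The interferon call was lost, at adjusted p up to 0.463, without aged KO replicate 1 or 3, aged WT replicate 1, 3, 4 or 5, young KO replicate 2 or 3 or young WT replicate 3. The granulocyte call was lost, at up to 0.369, without aged KO replicate 3 or 6, aged WT replicate 1, 3 or 6, young KO replicate 1 or 4 or young WT replicate 1 or 3. The HOX call was lost, at up to 0.112, without aged KO replicate 1, aged WT replicate 4 or 5, young KO replicate 1 or 2 or young WT replicate 4. The immediate early call was lost, at up to 0.106, without aged KO replicate 3, aged WT replicate 6 or young KO replicate 2 or 3. The DNA damage call was lost without young KO replicate 2 or young WT replicate 4 (up to 0.0783), the DNA replication call without young KO replicate 1 or young WT replicate 1 (up to 0.138), and the heat shock call without young WT replicate 1 (0.138).

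Aged and young WT cells differed in most of the genes measured. Vwf, the von Willebrand factor gene, was 17.6-fold higher in aged WT cells (875 ± 145 against 49.4 ± 12.6 CPM, SD, n = 6 and 4). The receptor gene Neo1 rose from 3.61 ± 0.86 to 81.6 ± 13 CPM and Clu from 30.7 ± 12.8 to 405 ± 66.8 CPM. Flt3 fell from 65.6 ± 7.94 to 17.1 ± 3.78 CPM and Cd34 from 532 ± 19.1 to 180 ± 28.4 CPM. The 10 largest falls among genes that met the naming rule, with a mean of at least 5 CPM, were in genes of neutrophils, and S100a8 was 44.4-fold lower in aged WT. Each age has its own table of counts, and no library of an age lies in the other table, so age and table cannot be told apart and every value here covers both.

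Of 15869 genes tested, 10799 differed between aged and young WT cells, 5579 higher and 5220 lower in aged, and 4515 passed a 2-fold minimum. In the HSC ageing up list 54 of 58 genes rose and 1 fell (54 and 1 adjusted over the list alone; median 2.33, camera adjusted p = 6.62e-19). This list also passed with an estimated correlation (adjusted p = 0.0218). The other 13 called lists in WT did not pass that way. In the HSC ageing down list 27 of 29 fell and 1 rose, as it was adjusted over the list alone (adjusted p = 3.7e-08, adjusted p = 0.386 with an estimated correlation). The list genes come from prior knowledge of stem cell ageing and were not chosen on these libraries. Of the ageing down genes, 10 are also in the DNA replication list and 7 in the lymphoid priming list, so these lists are not separate results. LT-HSC identity genes rose in 21 of 30, with Mecom from 90.9 ± 18.2 to 294 ± 24.0 CPM, and 2 fell (adjusted p = 0.000122, adjusted p = 0.386 with an estimated correlation). Lymphoid priming genes fell in 16 of 21, and 3 rose (adjusted p = 0.00436, adjusted p = 0.386 with an estimated correlation).

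Cell cycle genes fell: 32 of 34 DNA replication genes, such as Rfc2 (-1.54), and 27 of 32 mitosis genes, such as Birc5 (-1.78; adjusted p = 5.36e-10 and 1.18e-06, and adjusted p = 0.633 and 0.694 with an estimated correlation). All 50 nuclear oxidative phosphorylation genes fell, with Ndufb7 at -1.60 (adjusted p = 1e-17, adjusted p = 0.413 with an estimated correlation). Cytosolic ribosomal protein genes fell in 45 of 77, MYC targets in 22 of 30 while 3 rose, and ribosome biogenesis genes in 26 of 40 while 6 rose (adjusted p = 9.02e-05, 0.000134 and 0.00638, and adjusted p = 0.75, 0.694 and 0.75 with an estimated correlation). HOX and cofactor genes rose in 13 of 19 and 3 fell, with Hoxb6 from 1.26 ± 0.47 to 11 ± 0.42 CPM (adjusted p = 0.0276, adjusted p = 0.413 with an estimated correlation, and adjusted p = 0.0513 without aged WT replicate 4). Cytokine receptor genes rose in 16 of 31 and 4 fell, with Il6st from 23.2 ± 7.18 to 109 ± 8.19 CPM (adjusted p = 0.0421, adjusted p = 0.694 with an estimated correlation). That call was lost without aged WT replicate 2 or 3 or young WT replicate 1 or 2, at adjusted p up to 0.065.

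Markers of other blood cells moved with age as well. Granulocyte and monocyte genes fell in 22 of 28 and 3 rose (adjusted p = 0.000393, adjusted p = 0.694 with an estimated correlation). S100a8 lay between 730 and 1516 CPM in the 8 young libraries and between 1.70 and 85.4 CPM in the 12 aged ones. Ngp fell from 1949 ± 657 to 32.9 ± 26.0 CPM, Camp from 582 ± 202 to 9.92 ± 8.27 CPM, Chil3 from 488 ± 113 to 7.88 ± 4.74 CPM and Ltf from 844 ± 324 to 25.7 ± 21.1 CPM. Wfdc21, Fcnb, Itgb2l, S100a9 and Chil1 completed the 10 largest falls under the naming rule, with log2 fold changes from -5.98 to -4.84. B cell and plasma cell genes fell in 13 of 19, such as Cd79b at -1.01, and 2 rose (adjusted p = 0.0178, adjusted p = 0.694 with an estimated correlation). Immunoglobulin genes went the other way: Igha was 148 ± 105 CPM in aged WT and 0.115 ± 0.16 in young WT, and Jchain 42.9 ± 21 and 0.469 ± 0.253 CPM. The other largest rises under the naming rule, Osmr, Rbpjl, Kcnb2, Matn4, Gabra4, Syt15, Tacr1 and Chrm3, reached 9.43 to 116 CPM in aged WT from means under 1 CPM in young WT. Rbpjl and Matn4 overlap each other in antisense, as do Gabra4 and Gabrb1. Of the 20 lists that did not pass, 2 had a median, mean and test that differed in sign.

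**Figure D4:**
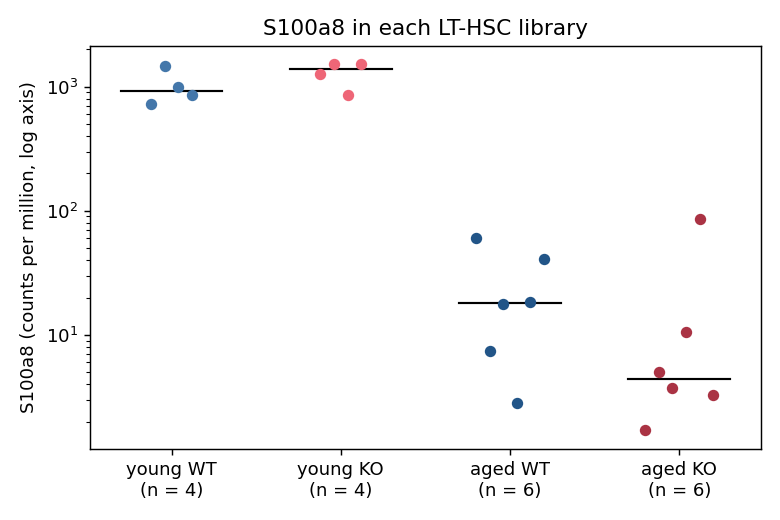
S100a8 in CPM on a log axis (y axis) for each library, by age and genotype (x axis). Points are libraries and bars are medians. The young libraries lie between 730 and 1516 CPM and the aged ones between 1.70 and 85.4 CPM.

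The same comparison in KO cells gave 11092 genes, 5682 higher and 5410 lower in aged KO, and 4768 passed a 2-fold minimum. HSC ageing up genes rose in 51 of 58 and 1 fell (median 2.19, camera adjusted p = 1.9e-15, adjusted p = 0.0557 with an estimated correlation), with Vwf at 960 ± 138 against 52.3 ± 7.63 CPM and Amotl2 at 86.8 ± 11.3 against 6.90 ± 0.84 CPM. HSC ageing down genes fell in 25 of 29 and 1 rose, with Flt3 from 59.2 ± 2.23 to 7.02 ± 2.11 CPM (adjusted p = 5.71e-07, adjusted p = 0.462 with an estimated correlation). Oxidative phosphorylation genes fell in 50 of 50, replication genes in 31 of 34 while 2 rose, mitosis genes in 27 of 32, ribosomal protein genes in 55 of 77 while 1 rose and MYC targets in 17 of 30 while 3 rose. Granulocyte genes fell in 23 of 28, lymphoid priming genes in 15 of 21 while 3 rose and lysosome genes in 16 of 32 while 4 rose, and identity genes rose in 22 of 30 while 2 fell. These 9 lists had camera adjusted p between 2.36e-16 and 0.0289, and adjusted p between 0.462 and 0.718 with an estimated correlation. The lysosome call was lost without aged KO replicate 5 (adjusted p = 0.0504). Among genes with a mean of at least 5 CPM that met the naming rule, and apart from immunoglobulin genes, Tacr1, Mab21l2, Ptprb, Ccn1, Cldn5, Dnm3, Rbpjl and Matn4 rose most, and Camp, Ngp, Chil3, S100a8 and Cxcl12 were among the 10 that fell most under it. Of the 23 lists that did not pass, 4 had a median, mean and test that differed in sign, as had 4 of the 22 that did not pass for the difference between the ages.

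On a scale common to all libraries, the HSC ageing up score was 1.17 ± 0.14 in aged WT, 0.70 ± 0.22 in aged KO, -1.36 ± 0.11 in young WT and -1.45 ± 0.13 in young KO. The age difference was 2.54 in WT and 2.15 in KO, or 84.7% of that in WT. Of the genes that differed with age in WT and with genotype in aged mice, 533 were lower in aged KO and higher in aged WT than in young WT, where lists drawn independently would share 368. The other pairings held 311 genes higher in both (273 independently), 205 higher in KO and lower with age (248) and 243 lower in both (335). Both comparisons share the aged WT libraries. Across 15869 genes, which are not independent replicates, the covariance of the KO effect in aged mice with the age effect in WT was -0.0551. In 1000 simulated sets of unchanged groups that share those libraries it averaged -0.0240 and ranged from -0.0277 to -0.0206. The simulation drew each gene independently, while genes of real libraries vary together. Its range is therefore too narrow to judge the observed value by. With the aged WT libraries split so that none was shared it was -0.0379 and -0.0365. The observed value minus the simulated mean was -0.0311, with a jackknife SE of 0.0283. Pearson's r was -0.128 observed and -0.448 in the simulation. These r values cannot be compared, because the simulated groups had no age difference and the real one widens the spread of the fold changes.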

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

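The tests of megakaryocyte genes, neutrophil RNA, the 2 count tables and Phf6 in aged KO replicates 5 and 6 were chosen only after the result was seen.

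Of 260 groups of libraries examined, 12 held a library far from the others of its group. Chance gives about 1 in 20, so that number is about what chance alone would give. Young KO replicate 3 had the most counts (19.3 M, where the other young KO libraries had 6.29 to 8.47 M), and young WT replicate 4 had 0.341% mitochondrially encoded counts. On the log2 CPM scale, Cd248 was 3.49, Clu 9.08 and Bcam 6.12 in aged WT replicate 2, and Nupr1 was 7.96 and Nfkbia 7.90 in aged WT replicate 5. Ccdc60 was 4.22 in aged KO replicate 6, and Bcam was 2.31 in young KO replicate 3. Dsc2 was -0.79 in young WT replicate 2, and Krt80 was 2.11 and Serpinf1 7.68 in young WT replicate 4.

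The KO effect differed between aged and young mice, by a test of the difference itself, for 48 genes. Those named were Gimap3 (2.01), Adgre4 (1.72), Neto2 (1.2), Igf2bp2 (1.16), Nefh (1.09), Dpp4 (-1.76), Smagp (-1.75), Pcp4l1 (-1.63), Hpgds (-1.58) and Ggt5 (-1.25), as log2 fold changes. The HSC ageing up score was flagged too (-0.39) at an unadjusted exact permutation p of 0.0401, which did not hold over the 5 scores tested (adjusted p = 0.201). That permutation assumes no KO effect at either age, so it does not test equality of the effects alone. Also flagged were 12 list medians: HSC ageing up (-0.39), granulocyte (-0.42), HOX (-0.17), lysosome (-0.15), DNA replication (0.21), immediate early (0.34), interferon (0.10), DNA damage (0.13), heat shock (0.19), ribosome biogenesis (0.22), MYC (0.21) and cholesterol (0.28). The list medians are those that passed camera with a preset correlation, 0 of them passed with an estimated correlation (lowest adjusted p = 0.474) or with fry (0.107), and the interferon and granulocyte calls were each lost without 9 of the 20 libraries. Of 100 splits of the genotype labels within each age, 8 gave as many genes as the real 48, so chance is not excluded for that count. The highest other split gave 194, several times the real count, and its source was not traced. These splits shuffle the KO effect within each age as well, so they do not test the difference between ages alone.

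In aged mice the real split gave 1758 genes, 1 of 100 splits gave as many, which was the real one, and the highest other gave 5. In young mice the real split gave 26, 1 of 35 splits gave as many, and the highest other gave 4. For age in WT and in KO the real splits gave 10799 and 11092, 1 of 100 splits gave as many in each, and the highest others gave 5308 and 6930. A rank of 1 in 35 or 1 in 100 makes chance unlikely for these 4 counts but does not exclude it. In young mice 1 of 35 is also the smallest share possible.

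HSC ageing up genes were lower in aged KO (score -0.47). With a trend in gene length and GC content removed from each library, the score difference was -0.49, which argues against that trend as the cause. A loss of megakaryocyte-like cells or their RNA remains open: the 21 megakaryocyte genes outside the list had a median log2 fold change of -0.0030 (SD 0.633 over genes, 4 higher and 2 lower), and members that go both ways decide nothing. An effect of genotype on the cells, and a change in which cells pass the CD150 gate, where Slamf1 itself fell, both remain open and were not tested.

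The age difference in WT covers 10799 genes. With a length and GC offset 10452 genes were called, which argues against that trend as the cause of that count. The list tests with age were not rerun with the offset, so the trend was not tested for them. Neutrophil RNA in the young libraries was predicted to dilute lymphoid priming genes there and so raise them in aged ones. Of 21 such genes, 16 were called lower and 3 higher. TMM scaling offsets a dilution shared by most genes, so this result cannot decide the question. Neutrophil RNA remains open as a cause, also for neutrophil genes themselves (S100a8 at 730 to 1516 CPM in young libraries), although the sort removed lineage-positive cells. Because 0 libraries of an age lie in the table of the other age, a batch difference and age cannot be told apart.

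Phf6 stood at 54.3 and 53.1 CPM in aged KO replicates 5 and 6. A candidate explanation is cells that kept Phf6: along the genes called without each library, their changes were 0.675 and 0.742 of the mean of the other aged KO libraries, and their Phf6 levels give 0.707 and 0.722. By the same measure replicates 2, 3 and 4 also lay within 2 SD of the share their Phf6 gives, but replicate 1 did not (1.084 against 1.199, -2.13 SD), so the agreement is not seen in all 6 libraries. A swap with an aged WT library is argued against, since the lowest aged WT library had 117 CPM. Incomplete deletion within each cell remains open and was not tested.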

How the results depend on the processing

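The length and GC offset and the fits without aged KO replicates 5 and 6 together were chosen only after the result was seen. Between genotypes within an age, Phf6 kept its direction and its call under every alternative run. The count in aged mice was 395 with a 2-fold minimum, and from 1434 to 2245 under the others except leaving out single libraries. The young count was 97 with no filter, 105 with DESeq2, 109 with voom quality weights, 15 with a 2-fold minimum, 9 with the replicate block and 55 with all 4 groups in the fit. The count for the difference between ages was 139 with DESeq2, 100 with voom quality weights, 30 with a 2-fold minimum, 30 with the replicate block and 121 without aged KO replicates 5 and 6. Age counts with a 2-fold minimum were 4515 in WT and 4768 in KO. Fewer genes can pass where a minimum is added, and otherwise the cause was not tested. Replicate numbers do not pair the libraries (r from -0.253 to 0.186 in aged mice), so the replicate block serves only as a check. With an estimated correlation 0 lists passed in the aged, young and difference comparisons and for age in KO, and 1 for age in WT. With fry 8 passed in aged mice, 0 in young mice, 0 for the difference, 24 for age in WT and 23 for age in KO. Leaving out each library gave 1379 to 1722 genes in aged mice, 2 to 19 in young mice, 12 to 74 for the difference, 10377 to 10651 for age in WT and 10591 to 10974 for age in KO. Lists then numbered 6 to 13, 4 to 10, 9 to 13, 13 to 16 and 10 to 12, in the same order. In young mice 10 lists passed without young KO replicate 3 or without young WT replicate 3. Phf6 ranged from -2.23 to -1.87 in aged and from -2.59 to -2.43 in young mice. The HSC ageing up score ranged from -0.51 to -0.39 in aged and from -0.16 to -0.03 in young mice, and the ageing down score from -0.17 to -0.03 and from -0.18 to -0.13. That last score passed without young WT replicate 3 (-0.18, exact permutation p = 0.0286). Under the length and GC offset Pfkp reversed with age (-0.10 in WT and -0.21 in KO), as did Dnmt3a in KO (-0.18), and the offset itself moves genes by length and GC. Of the values for single genes under alternatives, leaving out Phf6 between genotypes within an age (45 values, which kept both), 17165 kept direction and side of the threshold, 564 lost their call, 150 gained one and 3 reversed. Library totals from 6293783 to 19297867 limit calls for genes near the filter.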

Other observations

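The test of fetal-stage genes was chosen only after the result was seen, and the permutation tests along the age difference were planned.

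Lin28b, an RNA-binding protein gene active in fetal blood stem cells, was singled out after its values were seen, since it had the smallest p in aged mice but lay below the level the naming rule asks for. Lin28b stood at 5.97 ± 1.31 CPM in aged KO and 0.324 ± 0.103 in aged WT (SD, n = 6 each; log2 fold change 4.15 ± 0.25, SE, adjusted p = 1.59e-07). In young mice it did not pass (1.39, adjusted p = 0.316), and the difference between ages did (2.76, adjusted p = 0.00782). Igf2bp2, another RNA-binding protein gene, rose in aged KO (1.23 ± 0.10, adjusted p = 1.92e-06).

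A wider fetal programme may underlie these rises. Of 9 other fetal-stage genes tested, 2 rose, Hmga1 (0.49) and Peg3 (1.09), and 2 fell, Dlk1 (-2.40) and Meg3 (-2.22), with a median of 0.06. Members that go both ways leave this open, and an effect of genotype at that age was not tested further.

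The hypothesis that the KO effect runs against the age difference across all genes was tested by permuting genotype labels within an age. The covariance with the age difference averaged over genotypes was 0.00565 in aged mice (exact permutation p = 0.827) and -0.00973 in young mice (exact permutation p = 0.8286), two-sided. An age difference averaged over genotypes itself holds part of the KO effect. That part moves the covariance upward in aged mice and downward in young mice, so its sign cannot decide whether the KO effect runs against age. The planned rule that such a p would exclude the relation was wrong, because a p that misses the threshold excludes nothing, so the question stays open.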
